A study of Danio rerio with 6 samples.

How the data were processed

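RNA was measured in the ventricle apex of adult zebrafish of the AB strain whose hearts had been cryoinjured, that is, frozen locally with a cold probe. Per the labels' protocols, fish received RO, an inhibitor of gamma secretase, or its DMSO carrier into the peritoneal cavity 24 h and 48 h after injury. Gamma secretase is the protease that cleaves Notch receptors and frees their intracellular domain. Apices were taken at 72 h and 3 hearts were pooled per library, with 3 libraries per group. The DMSO libraries carry replicate numbers 1, 2 and 3 and the RO libraries 2, 3 and 4. Libraries were made from polyA RNA with a TruSeq kit, per the labels' protocols.

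The submitters' processing notes name CASAVA 1.8, cutadapt 1.6.1, Bowtie2 2.0.6, RSEM 1.2.3, edgeR and the Zv9 genome build, without saying how each was used. The annotation release and the use of strand in counting are not given in the sources used here, so reads of a gene and of an overlapping or antisense gene were not told apart. Reads of near-identical paralogs, such as the cardiac myosin heavy chains and the actins, can be split between copies in these values.

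The authors deposited 1 table with 14211 gene IDs and a scaled signal per gene and library. Its values are whole numbers of reads divided by 1 factor per library: 100% of the values in each library came out whole within 0.01 read. The scale is that of CPM on an effective library size, with column sums from 971801 to 1036454. Every gene in the table lay above 1 in at least 3 libraries. The reads recovered per library were 3997595, 4015878 and 3306018 for DMSO replicates 1, 2 and 3, and 3649538, 4463303 and 4160585 for RO replicates 2, 3 and 4. They count only the reads assigned to these genes. One read was worth a value of 0.219 to 0.298, so genes at values near 5 rest on few reads and carry a large counting error.

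Gene symbols came from a table that pairs gene IDs with symbols: 11589 of the 14211 IDs had one. There were 576 symbols that stood for more than 1 ID, together 1159 IDs, and the ID is printed for such genes. Symbols are printed as that table gives them, often in the form of the human orthologue. No genome was used and no coordinates are given.

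The design expected scaled values or counts, and the test for scaled values was used. Values were taken as log2(value + 0.5) with no further scaling and tested with limma 3.58.1 (limma-trend, R 4.3.3) for RO minus DMSO, without covariates. The planned minimum of 1 in 3 libraries removed no gene. P-values were adjusted by the Benjamini-Hochberg method over all 14211 genes, and the threshold was an adjusted p of 0.05. Every adjusted p for a gene is from this test unless another tool is named. Fold changes are differences of mean log2(value + 0.5) turned into ratios, so they can differ from the ratio of the printed means and understate the change of low genes. Levels are printed as mean ± SD of the deposited values.

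There were 24 gene lists, with 899 symbols, fixed before the data were examined. They cover Notch signalling, the cell types of an injured ventricle, other tissues that dissection can bring along, inflammation, signalling, metabolism, the cell cycle and stress. Of these symbols 616 were matched, 448 by the same symbol, 83 by a synonym, 83 by the stem of a paralog name and 2 by an orthologue. The rules of matching were set after the names, but before any test, had been seen. Lists were tested against all other genes with camera at its preset correlation of 0.01, adjusted over the 24 lists, and again with a correlation estimated from the data. The fry test of limma asked whether the genes of a list move one way on balance, or in either direction (mixed). Per list, the passing members were counted at adjusted p over all genes and adjusted over the list alone.

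The named genes follow a rule fixed before the data were examined: the 10 highest and 10 lowest log2 fold changes among genes with a symbol that pass the threshold, whose groups do not overlap and whose mean level is at least 5. For each list up to 4 passing members were added, by smallest p, or the 2 with the highest level where none passed. A set of 19 Notch, endothelial and immune symbols was to be reported whatever their p. Of these, 15 were matched; hey1, heyl, ncstn and mpx were not analysed here, and some of the 15 are not reported here. The symbols nrarpa and nrarpb were matched to the 2 NRARP IDs, and notch1a and notch1b to the NOTCH1 ID, so paralogs were not told apart there. Genes singled out after their values were seen are named as such where they appear.

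Libraries of a group were compared pairwise. Their chi-square per degree of freedom on the recovered reads was 5.02 to 11.7, so no library repeated another, and rank correlations within groups were 0.961 to 0.972.

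The alternatives were other pseudocounts, minimum values, scalings, limma settings and thresholds, a block for the replicate number, each library left out in turn, and edgeR 4.0.16 and DESeq2 1.42.0 on the recovered reads. Their effect is given in the closing section. Under the block, DMSO replicate 1 and RO replicate 4 share their number with no library of the other group. The blocked contrast therefore rests on replicates 2 and 3 alone. Groups are 3 pools of hearts each, and nothing in the labels gives a batch. The gene p-values of limma weigh the spread between pools (4 residual degrees of freedom) with that of other genes of like level (7.02 prior degrees of freedom). Camera at its preset correlation compares members with all other genes, so its p-values do not directly measure the spread between pools.

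The test was checked on simulated reads with 200 changed genes among 14211 in 5 simulations of this comparison. Changed genes were drawn only from those with a mean level of at least 5, so recovery of lower genes was not checked. It recovered 17.9% of genes changed 1.5-fold, 69.0% of those changed 2-fold and 92.4% of those changed 3-fold, with 9.01% of its calls false. Simulations with no change gave 4 called genes in 5 runs and 0 called lists. Genes were drawn independently there, while members of the real lists correlated, by up to 0.91 for ribosomal proteins. The 0 therefore does not check the list test. With 17.9% recovered, absence from the called genes says little about changes near 1.5-fold.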

Results

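The data are 6 RNA libraries from cryoinjured ventricle apex of adult zebrafish, 3 from fish given the gamma secretase inhibitor RO and 3 from fish given DMSO. Each library is a pool of 3 hearts taken 72 h after injury. The comparison asks which transcripts of the injured apex differ between fish given RO and fish given DMSO from 24 h after injury. Cleavage of Notch receptors was not measured in these data. Between 3306018 and 4463303 reads per library stand behind the values. The first principal component of the 1000 most variable genes held 31.0% of their variance and separated the groups, with RO replicate 2 farthest from the DMSO libraries (23.6, against 6.70 and 10.2 for RO replicates 3 and 4). Mitochondrially encoded genes took 10.60%, 11.96% and 11.26% of the reads in the DMSO libraries and 10.72%, 10.03% and 11.14% in the RO libraries.

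Of 14211 genes, 147 passed the threshold, 92 higher and 55 lower in RO. Genes of endothelium and a versican gene were among those higher. Some growth arrest genes, a cardiac BMP ligand gene and a myosin heavy chain gene were among those lower. Growth arrest genes were not tested as a group of their own. All 147 had groups that did not overlap, as did 18.7% of all genes, where chance gives 10%. At an unadjusted p below 0.05 there were 1905 genes. The number rests on how the spread is modelled: without the mean-variance trend of limma 1 gene passed. It was the protocadherin gene PCDH18 (ENSDARG00000089805), named after its values were seen, at 4.56 ± 0.958 in DMSO and 0.401 ± 0.108 in RO (SD, n = 3). The edgeR quasi-likelihood test on the recovered reads called 156 genes, 146 of them among the 147, and DESeq2 called 240. It fell to 59 genes without DMSO replicate 1, 22 without DMSO replicate 2, 95 without RO replicate 2 and 52 without RO replicate 3, and was 101 without DMSO replicate 3 and 105 without RO replicate 4.

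NR4A3 (ENSDARG00000055854), an orphan nuclear receptor of the immediate early class, rose 6.67-fold, from 28.8 ± 28.4 to 143 ± 12.3 (SD, n = 3 per group here and below; adjusted p = 0.0323). The DMSO libraries of NR4A3 lay far apart: its log2 fold change was 2.74, and 3.50 without DMSO replicate 3 and 2.19 without DMSO replicate 1. PELI1 (ENSDARG00000091592), a ubiquitin ligase of innate immune signalling, rose 5.02-fold to 28.5 ± 9.91. The Krüppel-like factor gene KLF4 (ENSDARG00000079922) rose 3.87-fold to 14.0 ± 2.56, and klf2b (ENSDARG00000040432), of the same family and responsive to blood flow in endothelium, 3.24-fold, from 117 ± 54.1 to 356 ± 49.4. EGLN3 (ENSDARG00000032553), a prolyl hydroxylase that acts on hypoxia-inducible factors, rose 3.21-fold to 37.8 ± 8.56. SPTLC2 (ENSDARG00000074287), a subunit of the enzyme that starts sphingolipid synthesis, rose 3.09-fold, from 39.4 ± 7.53 to 121 ± 9.35 (adjusted p = 0.00187). The matrix proteoglycan gene vcanb (ENSDARG00000009401) rose 2.60-fold, from 34.3 ± 6.30 to 89.2 ± 7.31 (adjusted p = 0.00262). TPPP3 (ENSDARG00000030463), which promotes tubulin polymerization, the small heat shock gene hspb9 (ENSDARG00000078674) and the adrenomedullin receptor gene CALCRL (ENSDARG00000011571) rose 3.66-, 3.02- and 2.52-fold, each from a DMSO mean below 12. SPTLC2 and vcanb passed without any 1 library. The other 8 did not: leaving out DMSO replicates 1, 2 and 3 ended 5, 8 and 1 of the 10 calls, and leaving out RO replicates 2, 3 and 4 ended 2, 5 and 5, with adjusted p up to 0.131. Robust empirical Bayes ended the calls of NR4A3, PELI1, klf2b and hspb9, quantile normalization that of hspb9, and DESeq2 that of NR4A3.

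The 10 genes with the largest falls among passing genes with a symbol and a mean level of at least 5 were 2.56- to 3.49-fold lower. KLF11 (ENSDARG00000013794), a growth-restraining Krüppel-like factor of the TGF-beta response, was 2.88-fold lower, at 131 ± 16.3 in DMSO and 45.7 ± 9.94 in RO (adjusted p = 0.00284). The microtubule-associated gene mtus1a (ENSDARG00000071562) was 2.67-fold lower, at 119 ± 16.9 against 44.1 ± 4.1 (adjusted p = 0.00187). BMP10 (ENSDARG00000061769), a ligand of the BMP family made in heart muscle, was 2.91-fold lower, at 29.8 ± 4.95 against 9.96 ± 2.06. The immediate early transcription factor egr1 (ENSDARG00000037421) was 2.7-fold lower, at 120 ± 17.3 against 47.5 ± 22.6, and the homeobox gene IRX2 (ENSDARG00000001785) was 2.7-fold lower, at 62.5 ± 18.8 against 22.4 ± 4.68. KLHL24 (ENSDARG00000008275), a substrate adaptor of a ubiquitin ligase, was 2.94-fold lower, the vasopressin receptor gene AVPR1A (ENSDARG00000045788) 2.79-fold lower, and the phosphatase gene UBASH3B (ENSDARG00000077399) 2.67-fold lower. The genes si:dkeyp-72g9.4 (ENSDARG00000073704) and si:dkey-182i3.10 (ENSDARG00000096614) were 3.49- and 2.56-fold lower. KLF11, mtus1a and si:dkeyp-72g9.4 passed without any 1 library. Leaving out DMSO replicates 1, 2 and 3 ended 5, 7 and 5 of the 10 calls and leaving out RO replicates 2, 3 and 4 ended 2, 4 and 3, with adjusted p up to 0.152. Robust empirical Bayes ended the calls of KLHL24 and egr1, array weights that of egr1, and quantile normalization those of UBASH3B and si:dkey-182i3.10.

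**Figure D1:**
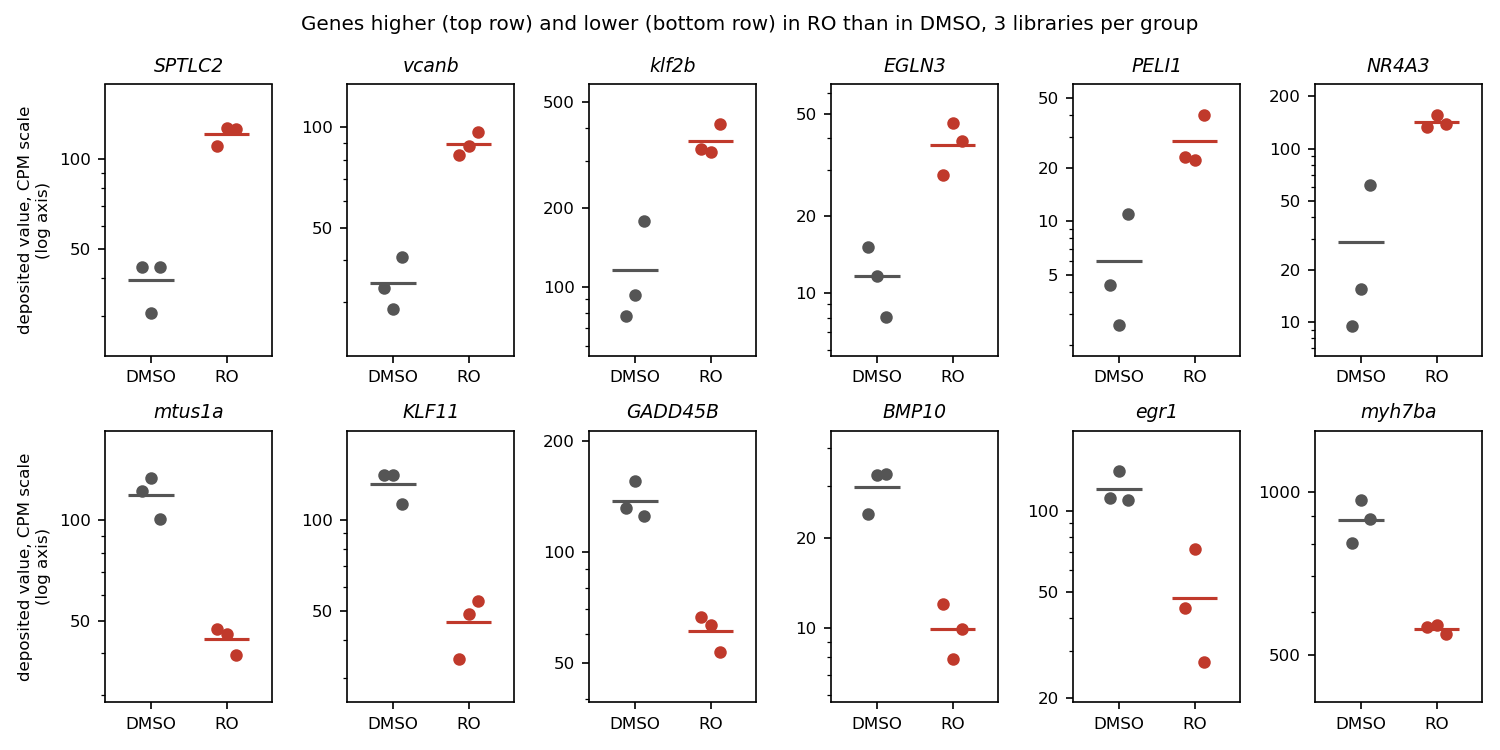
Scaled read values, on the deposited CPM scale and a log axis, of 12 genes in each library. Points are the 3 DMSO (grey) and 3 RO (red) libraries and bars are group means; the groups do not overlap for any gene shown, and the DMSO libraries of NR4A3 spread from 9.48 to 61.3.

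Notch target genes lay slightly lower in RO, and none passed over all genes. Of 10 measured IDs, 9 had log2 fold changes below 0, with a median of -0.23, and camera placed the list below the other genes (adjusted p = 0.0473 over the lists). That call was lost with an estimated correlation (adjusted p = 0.514). Adjusted over the list alone, 1 member passed, EFNB2 (ENSDARG00000020164), an ephrin ligand of arterial endothelium, at 41.4 ± 3.06 in DMSO and 27.7 ± 3.12 in RO (0.0877 over all genes). HEY2, a repressor downstream of Notch, stood at 10.99 ± 0.599 against 7.30 ± 0.644 (adjusted p = 0.221), and the ligand gene dll4 at 52.3 ± 8.14 against 41.45 ± 10.2 (adjusted p = 0.462). HES1, the symbol given for her6, had a log2 fold change of -0.24, and HES4, given for her9, of -0.0021 (95% interval -0.35 to 0.35). NRARP stood at -0.27 (ENSDARG00000091419) and 0.048 (ENSDARG00000018958), and the glycosyltransferase gene LFNG at -0.057. Leaving out a single library ended the list's call in 4 of 6 cases, with adjusted p of 0.101 without DMSO replicate 2, 0.110 without DMSO replicate 3, 0.174 without RO replicate 3 and 0.113 without RO replicate 4. Its median was -0.39 without RO replicate 2 and -0.14 without RO replicate 3 or 4. The call also ended with the replicate number as a block (0.0868), with fry (0.136) and with list symbols matched by symbol alone (0.107). The direction of LFNG turned without DMSO replicates 2 or 3, that of NRARP (ENSDARG00000018958) without DMSO replicate 2, and that of HES4 without DMSO replicates 2 or 3 or RO replicate 3, with median-of-ratios scaling and with array weights.

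Among the components of the Notch pathway itself, NUMB (ENSDARG00000027279), which antagonizes Notch receptors, rose 1.93-fold, from 29.7 ± 4.5 to 57.2 ± 2.69 (adjusted p = 0.0122). It was the 1 of 22 measured members that passed, over all genes and adjusted over the list alone. Its call ended without DMSO replicate 2 or RO replicate 3, with adjusted p up to 0.0663. The list symbol dld, a Notch ligand, was matched to DLD (ENSDARG00000008785), which is also the human symbol of a mitochondrial dehydrogenase, so this member is doubtful. Without it the list's median was 0.087 and its camera adjusted p 0.865, and NUMB still passed over the list alone. The receptor genes NOTCH1, notch2 and NOTCH3 had log2 fold changes of 0.087, -0.048 and -0.61 and did not pass (adjusted p = 0.875, 0.910 and 0.229), nor did the gamma secretase subunit gene PSEN2, at 0.18 (adjusted p = 0.687). The directions of NOTCH1 and notch2 turned without DMSO replicate 1 or RO replicate 3. The list as a whole did not move one way (camera adjusted p = 0.943, median 0.028), while the mixed fry test, for change in either direction, gave an adjusted p of 0.00166, a test that 12 of the 24 lists passed.

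Markers of endothelium and endocardium were higher in RO. Of 28 measured, 21 lay above 0 and 3 rose at the threshold: klf2b, plvapb, which encodes a protein of vessel diaphragms, from 27.18 ± 2.40 to 45.8 ± 2.59 (1.68-fold, adjusted p = 0.0302), and the VEGF receptor gene flt1, from 67.4 ± 9.80 to 119 ± 21.0 (1.75-fold, adjusted p = 0.0356). As many as 7 passed adjusted over the list alone, all higher. These include klf2a, at 175 ± 75.0 against 358 ± 25.2 (adjusted p = 0.0654 over all genes), and the junction gene CLDN5 (ENSDARG00000014059), at 24.0 ± 2.64 against 53.4 ± 18.5, singled out after its values were seen (0.0607 over all genes). The list's median log2 fold change was 0.31 (camera adjusted p = 1.1e-04). With an estimated correlation the call was lost (adjusted p = 0.286), though the estimate, 0.0114, lay near the preset of 0.01. A higher correlation between members thus does not account for that loss. Without DMSO replicate 1 the call was kept at a median of 0.21. The macrophage and thrombocyte lists also lay higher on average in RO, as given below, though the macrophage list mean of RO replicate 3 (5.73) lay below those of DMSO replicates 1 and 2 (5.74 and 5.83). The call of klf2b ended without DMSO replicate 2 (adjusted p = 0.0663), that of plvapb without DMSO replicate 1, DMSO replicate 2, RO replicate 3 or RO replicate 4 (up to 0.121), and that of flt1 with quantile normalization and without any library but DMSO replicate 1 (up to 0.121).

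Fibroblast and matrix genes were lower as a list at the preset correlation. Of 35 measured, 29 lay below 0 and 6, vcanb among them, above, with a median of -0.30, and camera placed the list below the other genes (adjusted p = 2.2e-04), a call that was lost with an estimated correlation (adjusted p = 0.414) and with the replicate block (0.0557). Over all genes only vcanb passed, and it rose. There were 7 lower members and 1 higher member adjusted over the list alone. Among the lower ones, named after their values were seen, were the collagen gene COL1A2, at 1538 ± 143 in DMSO and 1036 ± 196 in RO (adjusted p = 0.108 over all genes), and SPARC, which encodes a collagen-binding protein, at 475 ± 31.8 against 343 ± 49.7 (adjusted p = 0.113). Markers of epicardium, the outer layer of the heart, did not pass as a list (14 measured, median -0.22, camera adjusted p = 0.198), and no member passed. Without DMSO replicate 2 that list passed (median -0.31, adjusted p = 0.0341), and without DMSO replicate 3 its median was -0.025. ANXA2 and krt94, the most abundant, had log2 fold changes of 0.18 and 0.13, that of ANXA2 turning without DMSO replicate 2. Adjusted over the list alone 1 member passed, the epicardial transcription factor gene wt1b, singled out after its values were seen, at 18.7 ± 2.41 against 10.2 ± 1.85 (0.0723 over all genes).

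Among 33 cardiomyocyte genes, myosin heavy chains moved apart. The gene myh7ba fell 1.58-fold, from 887 ± 81.8 to 560 ± 10.9 (adjusted p = 0.0255), and MYH6 (ENSDARG00000079564) rose 1.6-fold, from 674 ± 93.3 to 1074 ± 116 (adjusted p = 0.0454). Reads of these paralogs can be split between copies, which leaves the single values uncertain. The list as a whole did not pass (median -0.14, camera adjusted p = 0.0767), but it did, downward, without DMSO replicate 1 or RO replicate 4 (median -0.21 in both, adjusted p = 0.0182 and 0.0114) and with the replicate block (-0.27, 0.00356). Without RO replicate 2 its median was -0.058. Adjusted over the list alone 2 members were higher and 3 lower. In the skeletal muscle list (11 measured, median 0.15, camera adjusted p = 0.288) the sarcomeric actin gene ACTC1 (ENSDARG00000057911), which heart muscle also expresses, rose 2.01-fold, from 357 ± 58.9 to 718 ± 122 (adjusted p = 0.0139); adjusted over the list alone, 2 members passed, both higher. In the list of smooth muscle of the outflow tract (12 measured) the actin-binding gene TAGLN (ENSDARG00000033466) rose 1.46-fold, from 224 ± 12.6 to 329 ± 33.5 (adjusted p = 0.0491), the only member to pass either way of adjusting. That list's median was -0.14 and its camera direction upward (adjusted p = 0.989). The call of myh7ba ended without DMSO replicates 2 or 3 or RO replicates 3 or 4 (adjusted p up to 0.104), that of MYH6 without any library but RO replicate 2 (up to 0.177), that of ACTC1 without DMSO replicates 1 or 2 (up to 0.0768) and that of TAGLN whichever of the 6 libraries was left out (0.0529 to 0.160). Quantile normalization also ended the calls of MYH6 and TAGLN, the replicate block that of MYH6, and a pseudocount of 0.1 and edgeR that of TAGLN.

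Markers of thrombocytes, the nucleated counterpart of platelets, showed the highest median of the lists, 0.49, with 10 of 11 measured members above 0 (camera adjusted p = 5.9e-05, and adjusted p = 0.332 with an estimated correlation, where the call was lost). Without DMSO replicate 3 the median was 0.76. FERMT3 (ENSDARG00000030938), needed for integrin activation in blood cells, rose 1.96-fold, from 8.70 ± 0.773 to 17.7 ± 3.68 (adjusted p = 0.0468). Adjusted over the list alone 4 passed, all higher, including the platelet receptor genes itga2b, at 30.9 ± 8.81 against 61.8 ± 22.7, and GP1BB, at 25.8 ± 3.43 against 44.9 ± 11.2, both singled out after their values were seen (adjusted p = 0.124 and 0.0915 over all genes). The call of FERMT3 was kept only without RO replicate 4, with adjusted p up to 0.178 without each of the others.

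Macrophage markers were higher as a list: 27 of 33 lay above 0 with a median of 0.25 (camera adjusted p = 2.2e-04), and the call was lost with an estimated correlation (adjusted p = 0.688) and without DMSO replicate 3 (median 0.15, adjusted p = 0.102). Without DMSO replicate 2 its median was 0.38. The amino acid transporter gene SLC7A7 rose 1.81-fold, from 39.1 ± 1.72 to 73.1 ± 20.6 (adjusted p = 0.0484), though without DMSO replicates 1, 2 or 3 or RO replicates 2 or 3 its call ended (adjusted p up to 0.137), as it did with quantile normalization and a pseudocount of 0.1. There were 5 members that passed adjusted over the list alone, all higher. They include MPEG1 (ENSDARG00000043093), the perforin-like gene of macrophages, at 18.8 ± 5.45 against 30.3 ± 3.92 (adjusted p = 0.141 over all genes). The second MPEG1 gene (ENSDARG00000055290) stood at 46.2 ± 14.0 against 52.8 ± 3.10. The protease gene CTSB (ENSDARG00000055120) at 333 ± 64.1 against 528 ± 135 and the integrin gene itgae.2 at 36.8 ± 5.02 against 61.8 ± 12.8, both singled out after their values were seen, were also among the 5.

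Other blood cells gave no call. Neutrophil markers (16 measured) had a median of 0.0026 and a mean of -0.0040, with an upward camera direction (adjusted p = 0.764); srgn and adam8a, the most abundant, had log2 fold changes of 0.26 and 0.0023, that of adam8a turning with quantile normalization and without DMSO replicates 2 or 3 or RO replicate 3. Erythrocyte genes (19 measured, median -0.11, camera adjusted p = 0.702) included hbaa1 at 840 ± 249 against 944 ± 418, whose direction turned with array weights and without DMSO replicate 2 or RO replicate 4, and SPTB at -0.11. Of 31 lymphocyte symbols 3 were measured (median 0.17, camera adjusted p = 0.614); GATA3 and il2rga had log2 fold changes of 0.17 and 0.19, that of il2rga turning without RO replicates 3 or 4. No member of these 3 lists passed over all genes or adjusted over the list alone.

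Inflammatory mediators moved in both directions. Of 31 measured, the TNF receptor family gene tnfrsf9a rose 2.28-fold, from 25.5 ± 8.16 to 58.3 ± 13.4 (adjusted p = 0.0360), and the chemokine gene cxcl12b fell 1.84-fold, from 58.0 ± 5.87 to 31.6 ± 5.39 (adjusted p = 0.0302). There were 4 higher and 6 lower members adjusted over the list alone. The list did not move one way (median -0.084, camera adjusted p = 0.702), while the mixed fry test gave an adjusted p of 4.0e-05, as 1 of the 12 lists that passed it. Genes singled out after their values were seen lay on both sides: the 2 prostaglandin synthase genes PTGS2 stood at 7.07 ± 2.29 against 15.7 ± 0.976 (ENSDARG00000010276) and at 33.3 ± 4.95 against 16.1 ± 6.19 (ENSDARG00000004539), tnfb at 3.11 ± 0.928 against 8.04 ± 0.50, and CXCL12 at 59.3 ± 4.79 against 35.06 ± 10.6, with adjusted p from 0.0567 to 0.0909 over all genes. The call of tnfrsf9a ended without DMSO replicates 1 or 2 or RO replicates 2 or 3 (up to 0.144) and that of cxcl12b without any DMSO replicate or without RO replicate 3 (up to 0.102).

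Interferon-response genes were higher as a list, with no single member passing over all genes. Of 19 measured, 15 lay above 0 with a median of 0.24 (camera adjusted p = 0.00283; adjusted p = 0.332 with an estimated correlation, where the call was lost). Without RO replicates 2 or 4 the median was 0.15 and 0.14, and with the replicate block 0.13, with the call kept in all 3. Adjusted over the list alone 4 passed, all higher, including the antiviral genes isg15, at 9.69 ± 1.43 against 16.7 ± 4.21, and mxa, at 21.3 ± 7.78 against 33.7 ± 1.34, both singled out after their values were seen (adjusted p = 0.169 and 0.177 over all genes). The most abundant members, b2m and stat2, had log2 fold changes of 0.072 and 0.070, that of b2m turning without DMSO replicate 1 or RO replicate 4.

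Immediate early and stress genes also moved in both directions. Besides NR4A3 and KLF4, which rose, the growth arrest genes GADD45B (ENSDARG00000027744) and BTG2 fell with egr1: GADD45B 2.23-fold, from 137 ± 15.9 to 61.2 ± 6.85 (adjusted p = 0.00309), and BTG2 2.23-fold, from 291 ± 33.3 to 133 ± 33.5 (adjusted p = 0.0152). Of 36 measured, 2 rose and 3 fell over all genes, and adjusted over the list alone 8 were higher and 5 lower. The list did not pass (median 0.030, camera adjusted p = 0.614). KLF6 (ENSDARG00000029072), singled out after its values were seen, stood at 257 ± 49.0 against 406 ± 44.6 (adjusted p = 0.0605). The call of GADD45B held without any 1 library, and that of BTG2 ended without DMSO replicate 2 (adjusted p = 0.0842).

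Growth factor and regeneration genes lay lower as a list of 31 (median -0.22, camera adjusted p = 0.0473; adjusted p = 0.332 with an estimated correlation, where the call was lost). The member that passed, both over all genes and adjusted over the list alone, was cxcl12b, which also belongs to the mediators. The list's call ended without DMSO replicate 1 (adjusted p = 0.0986) and RO replicates 2, 3 and 4 (0.0857, 0.0622 and 0.0755), with a median of -0.13 without the last. It also ended with the replicate block (0.103), with fry (0.107), with a minimum value of 5 (median -0.16, 0.137) and with list symbols matched by symbol alone (0.107). In the TGF-beta and BMP list (28 measured, median 0.060, camera adjusted p = 0.532) BMP10 fell, and adjusted over the list alone 1 member was higher and 1 lower. Its call ended without DMSO replicate 2 (adjusted p = 0.0548). The plasminogen list (10 measured, median 0.19, camera adjusted p = 0.269) had no member passing over all genes and 2 adjusted over the list alone. They include s100a10b, a partner of annexin A2 on the cell surface, at 853 ± 51.2 against 1149 ± 162 (adjusted p = 0.175 over all genes).

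Genes of mitochondrial energy production lay slightly lower as a list: 58 of 73 were below 0 with a median of -0.087 (camera adjusted p = 0.0473), and none passed alone. The call was lost with an estimated correlation (adjusted p = 0.951), with fry (0.623), with median-of-ratios scaling (0.0523), with list symbols matched by symbol alone (0.0760) and without DMSO replicates 2 or 3 or RO replicates 2 or 3 (0.437, 0.291, 0.0576 and 0.488). Its median was -0.15 without DMSO replicate 1, -0.050 without DMSO replicate 2 and, with the call kept, -0.19 with the replicate block (5.6e-04). ATP5F1B and MDH2 had log2 fold changes of -0.095 and -0.21. Glycolysis genes (26 measured) had a median of 0.0022, a mean of -0.020 and an upward camera direction (adjusted p = 0.876), with GAPDH at -0.40 and ALDOA (ENSDARG00000011665) at 0.038, which turned with quantile normalization and without DMSO replicate 3. Cell cycle genes (48 measured) did not pass as a list (median 0.084, camera adjusted p = 0.269), but they did, upward, without RO replicate 4 (0.25, 5.2e-04) and with the replicate block (0.20, 0.00734); tuba5 and HMGB2 stood at 0.27 and 0.016, that of HMGB2 turning with quantile normalization, with array weights and without DMSO replicates 1 or 3 or RO replicate 2. Ribosomal protein genes (68 measured) had a median of 0.053 (camera adjusted p = 0.167). They passed, upward, without DMSO replicate 2 or RO replicates 3 or 4 (adjusted p = 0.00239, 0.0406 and 0.00664) and with the replicate block (0.0179). Among them were RPS2 at 0.080 and RPLP0 at 0.14, both turning without RO replicate 2 and RPS2 also with quantile normalization. Of 41 liver symbols 4 were measured (median -0.10, camera adjusted p = 0.702), with tfa at -0.17 and c3a.1 at -0.039, the first turning without DMSO replicate 1 or RO replicate 3 and the latter with edgeR, with DESeq2 and without DMSO replicates 1 or 3 or RO replicates 2 or 3. No member of the lists in this paragraph passed over all genes or adjusted over the list alone.

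At the preset correlation 8 of the 24 lists passed, 4 higher and 4 lower, and with an estimated correlation or the directional fry test 0 did; 12 passed the mixed fry test. In 3 of the 10 splits of the 6 libraries into groups of 3, the real one among them, at least 8 lists passed at the preset correlation.

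**Figure D2:**
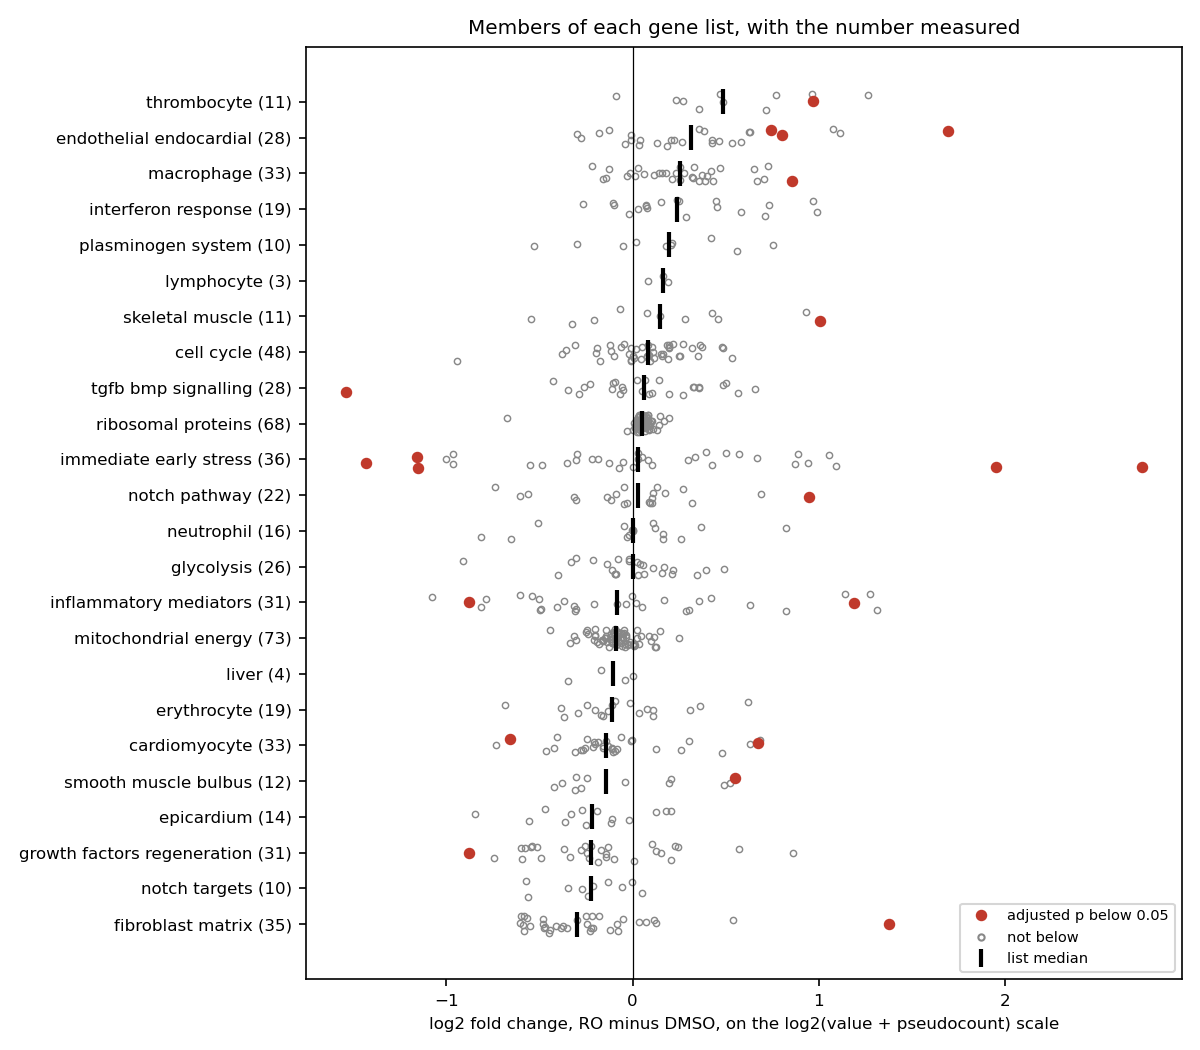
Log2 fold changes, RO minus DMSO, of the members of each list, with the number measured in brackets. Filled red points passed at adjusted p below 0.05 over all genes, open points did not, and the black bar is the list's median; the medians run from -0.30 in the fibroblast and matrix list to 0.49 in the thrombocyte list.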

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

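Settings chosen only after the data were seen were the unadjusted threshold, the matching of list symbols by symbol alone, and, for the lists, the minimum value of 5, median-of-ratios scaling, TMM scaling and the Notch pathway without DLD. The 147 genes stayed within 1.5 times that number with pseudocounts of 0.1 and 2 (138 and 160 genes), a minimum value of 5 (156), median-of-ratios, TMM and quantile scaling (148, 147 and 115), robust empirical Bayes (180), array weights (203) and edgeR (156). No scaling moved the median of all genes by more than 0.1 on the log2 scale. Without the mean-variance trend 1 gene passed, with adjusted p up to 0.216 among the 147, and the cause was not tested. DESeq2 gave 240 genes, 123 of them among the 147, and no adjusted p for 21 of the 147; the cause of its higher number was not tested. By construction, an adjusted p below 0.1 gave 318 genes, an added minimum of 1 for the absolute log2 fold change 76 and an unadjusted p below 0.05 1905. Without 1 library the number ran from 22 (DMSO replicate 2) to 105 (RO replicate 4), with 59, 101, 95 and 52 without DMSO replicates 1 and 3 and RO replicates 2 and 3. Fewer libraries leave fewer degrees of freedom, and 20 genes passed with all 6 libraries and without any 1 of them. Of 47 named genes that passed, 15 did so without any 1 library. In 793 comparisons 184 lost the call and none turned direction. The groups of these genes do not overlap, so leaving out a library could not turn a direction, and that part is no test. DESeq2 gave no adjusted p for 6 of the 47, and those comparisons are not among the 793. Of 986 comparisons for 58 named genes that had not passed, 888 gave the same result, 53 gained a call and 45 turned direction. The settings without a filter could not be run, since every gene already met the minimum. With 3 libraries per group at this depth, a change of 1.5-fold was mostly missed in simulated reads of genes with a mean level of at least 5. Depth was not varied there.

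Numbers 2 and 3 are shared by both groups, and deviations from the group means correlated by 0.116 for number 2 and 0.0913 for number 3. Those were the highest of the 9 correlations between groups, the others running from -0.116 to 0.0433. This is a hint from the data, not from the design: the labels do not say what a number marks and only 2 are shared, so the samples were not taken as pairs. With the replicate block 405 genes passed, 126 of them among the 147, and 8 lists, 5 of them among the original 8. DMSO replicate 1 and RO replicate 4 drop out of that contrast, as no library of the other group shares their number. The contrast rests on replicates 2 and 3 alone, with little spread of its own. It is therefore no check of the calls on all 6 libraries. Why more genes passed was not tested. Of the named genes, MYH6 and si:dkey-182i3.10 lost their calls under the block.

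For the lists, 8 passed at the preset correlation and 0 with an estimated correlation or with fry, while matching by symbol alone gave 5 and leaving out 1 library gave 5 (DMSO replicate 3) to 9 (RO replicate 4). The estimate was 0.0114 for endothelium and -0.012 for growth factors, near or below the preset of 0.01. A higher correlation does not account for those losses. It was 0.021 for interferon response, 0.092 for Notch targets and 0.10 for fibroblasts and matrix. The estimate was highest for thrombocytes, macrophages and mitochondrial energy, at 0.24, 0.32 and 0.39. The lists of thrombocytes, endothelium and interferon response lost their calls only with the estimated correlation and fry, out of 15 settings. The fibroblast and matrix list also lost it under the block, and the macrophage list without DMSO replicate 3. The Notch targets lost it in 8 settings, growth factors in 9 and mitochondrial energy in 8. Over the 8 lists 83 of 120 comparisons kept the call and none turned direction, and over the 16 lists that had not passed 195 of 239 gave the same result, 10 gained a call and 34 turned sign. The gains were 4 for ribosomal proteins, 3 for cardiomyocytes, 2 for the cell cycle and 1 for epicardium, each under the block or without 1 library. Without DLD, a doubtful member of the Notch pathway, 8 lists passed. Medians that turned sign belonged to lists that had not passed, and the cause was not tested. With quantile normalization they were -0.055 for glycolysis and -0.013 for immediate early genes. Under the block they were 0.085 for erythrocytes, -0.065 for glycolysis, 0.0067 for mediators, -0.055 for the Notch pathway and -0.089 for skeletal muscle. Matched by symbol alone they were -0.045 for glycolysis, -0.048 for the Notch pathway and -0.067 for skeletal muscle, and with a minimum value of 5 the Notch pathway stood at -0.031. Without 1 library the medians ran from -0.068 to 0.25 for the cell cycle, -0.23 to 0.21 for erythrocytes, -0.038 to 0.024 for glycolysis, -0.014 to 0.074 for immediate early genes, -0.21 to 0.065 for mediators, -0.40 to 0.062 for liver, -0.012 to 0.30 for lymphocytes, -0.15 to 0.23 for neutrophils, -0.032 to 0.056 for the Notch pathway, -0.042 to 0.12 for ribosomal proteins and -0.26 to 0.054 for outflow tract smooth muscle.

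Single genes that turned direction had not passed and lay near 0, and the cause was not tested. The log2 fold change of HES4 was 0.0019 with median-of-ratios scaling. With quantile normalization HMGB2 stood at -0.031, ALDOA (ENSDARG00000011665) at -0.091, adam8a at -0.040 and RPS2 at -0.037. With array weights HMGB2 stood at -0.014, hbaa1 at -0.089 and HES4 at 0.0058. For c3a.1 edgeR gave 0.30 and DESeq2 0.29. Under the block hbaa1 stood at -0.0023, b2m at -0.15 and NOTCH1 at -0.088. Without 1 library the values ran from -0.066 to 0.083 for HMGB2, -0.013 to 0.33 for ANXA2, -0.21 to 0.47 for hbaa1, -0.0027 to 0.068 for ALDOA (ENSDARG00000011665), -0.055 to 0.19 for b2m, -0.45 to 0.053 for tfa, -0.71 to 0.52 for c3a.1, -0.020 to 0.59 for il2rga, -0.15 to 0.15 for adam8a, -0.22 to 0.032 for LFNG, -0.20 to 0.14 for HES4, -0.020 to 0.16 for RPS2, -0.023 to 0.25 for RPLP0, -0.18 to 0.26 for NRARP (ENSDARG00000018958), -0.026 to 0.27 for NOTCH1 and -0.12 to 0.020 for notch2.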

Other observations

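The tests of a lower cardiomyocyte share, of macrophage number and of the number of genes over other splits were chosen only after the result was seen. Genes in the next paragraph are the 10 with the smallest p outside the fixed rule, 5 per direction, and were named after their values were seen.

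Several genes with small spread changed between 1.9- and 2.5-fold. CHST1, a sulfotransferase gene of keratan sulfate and cell-surface glycans, rose 2.39-fold, from 36.3 ± 1.22 to 87.6 ± 7.26 (SD, n = 3; limma adjusted p = 0.00187). CLIC2, of the intracellular chloride channel family, rose 2.23-fold, from 326 ± 34.1 to 728 ± 74.3, the actin-binding gene shroom4 2.21-fold, from 85.3 ± 13.4 to 188 ± 14.3, the myelin and membrane protein gene PMP22 2.46-fold, from 99.9 ± 23.1 to 243 ± 21.3, and si:rp71-1c10.7 2.0-fold, from 69.7 ± 4.86 to 140 ± 14.6. The transcription factor gene CEBPD fell 1.94-fold, from 243 ± 5.32 to 126 ± 12.8, and the growth arrest gene GADD45G 2.23-fold, from 103 ± 15.8 to 45.7 ± 3.80. The myosin heavy chain gene myh7bb fell 2.31-fold, from 708 ± 92.1 to 306 ± 26.2, in the same direction as myh7ba. HAS1, which makes hyaluronan, the polysaccharide that versican binds, fell 2.0-fold, from 76.4 ± 5.98 to 37.99 ± 2.75. The mitochondrial carrier gene SLC25A32 (ENSDARG00000089791) fell 2.43-fold, from 33.5 ± 5.09 to 13.5 ± 1.97, and its call alone among these 10 ended without 1 library, DMSO replicate 2 (adjusted p = 0.0632). Without the mean-variance trend of limma none of the 10 passed.

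The 6 libraries divide into groups of 3 in 10 ways, too few for a share below 0.05. The real division gave 147 genes and was the 1 split with a count as large, and the highest other gave 0 genes; at an unadjusted p below 0.05 the counts were 1905 and at most 760. For the lists at the preset correlation, 3 of the 10 splits gave at least as many as the real 8, and the highest other gave 8. The macrophage list passed in 5 other splits, the thrombocyte list in 4, and the endothelial, the fibroblast and matrix and the mitochondrial energy lists in 3 each. The Notch targets and the interferon response passed in 1 each and the growth factors in 0.

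Endothelial, macrophage and thrombocyte lists were higher in RO and the fibroblast and matrix list lower at the preset correlation of camera. With an estimated correlation none passed (adjusted p = 0.286, 0.688, 0.332 and 0.414), and the macrophage call also ended without DMSO replicate 3 (0.102) and that of the fibroblast and matrix list with the replicate block (0.0557). A smaller share of cardiomyocytes as the only change would raise all other cell types alike. The endothelial list mean less that of fibroblasts and matrix was instead higher in RO by 0.596 (SE 0.139). It stood at -1.52, -1.33 and -1.43 in the DMSO libraries and -1.06, -0.806 and -0.625 in the RO libraries. These lists were picked for lying apart, so the sign was known and the SE is no separate test. The values argue only against a smaller share as the sole cause. One acting with other changes stays open, and the cardiomyocyte list mean differed by -0.086 (SE 0.120). Read depth differed by at most 1.35-fold between libraries. With every library thinned to the reads of the shallowest, the difference of medians between these lists was 0.609 (SD 0.027 over 20 thinnings), against 0.611 unthinned. The thinning took up to 25.9% of a library's reads and moved the log2 fold change of a typical gene by 0.039. So small a thinning could hardly move a difference of that size in values scaled per library, which makes it a weak test. It shows only that unequal numbers of counted reads did not make the difference. A change in the number of macrophages cannot be told apart. Of the macrophage members 81.8% lay above 0, which was known from the list, and their SD of 0.271 decides little, since 30.9% of 1000 random lists of like level had a smaller one (median 0.298). The list means differed by 0.262 with an SE of 0.177. A change in the number of endothelial cells or thrombocytes, and an effect of the inhibitor within cells, stay open, as these pools hold no count of cells.

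Some growth arrest and stress genes, KLF11, GADD45B, CEBPD and BTG2 among them, were picked for being lower in RO. The fixed list of immediate early and stress genes did not move one way: its median was 0.030, 20 of 36 members lay above 0, 8 were higher and 5 lower adjusted over the list alone, and NR4A3 and KLF4 rose. For a difference in the hour of harvest, day-phase less night-phase clock genes differed by 0.397 (SE 0.130), below the bound of 1 set beforehand. That mean cannot decide on the hour, since members of both sets went both ways and can cancel in it. A difference in the hour stays open: the difference between the sets exceeds 2 SE. The clock gene PER2, singled out after its values were seen, rose 2.05-fold, from 44.1 ± 10.3 to 90.5 ± 17.4 (SD, n = 3, limma adjusted p = 0.0323). Its call ended without DMSO replicates 2 or 3 or RO replicates 3 or 4 (up to 0.104). The 17 day-phase IDs had a median log2 fold change of 0.21 and the 10 night-phase IDs -0.24. Both sets held members on either side of 0, such as the day-phase gene tefa at -0.72 and the night-phase gene bmal2 at 0.23. Lower glucocorticoid signalling cannot be told apart: the median of 21 other target genes was -0.085, and 9 lay above 0. Among the 21, and picked after their values were seen, fkbp11 fell (log2 fold change -1.03, adjusted p = 0.0430) and FKBP5 stood at 0.98 (adjusted p = 0.112). The call of fkbp11 ended with quantile normalization and without any library but RO replicate 4 (up to 0.143). The bound set beforehand added 2 SE to the median, which any median near 0 meets; with 2 SE subtracted the median reaches -0.38, beyond the -0.3 that the explanation needs.

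The prolyl hydroxylase gene EGLN3 is induced by hypoxia, so a wider hypoxia response was tested as a hypothesis. The mean of 28 other hypoxia targets differed between groups by 0.144 (SE 0.068), and 2 SE above it, 0.281, stayed below the bound of 0.3 set beforehand, with 16 of 28 members above 0. With 3 pools per group, however, 2 SE falls short of a 95% bound, and 0.281 lies close to 0.3. The test therefore cannot decide on a response of that size in the mean of the matched members. The list symbols ldha, pgk1, bnip3, ca9 and hk2, among others, matched no measured ID. The matched members went both ways, so a response of part of the targets stays open too. EGLN2, singled out after its values were seen, rose 2.05-fold, from 9.52 ± 2.39 to 19.8 ± 3.02 (adjusted p = 0.0468), a call that ended with quantile normalization and without any library but DMSO replicate 1 (up to 0.177). ANKRD37, PFKFB3 and ADM (ENSDARG00000069027), picked in the same way, had log2 fold changes of 1.34, 1.03 and 0.95 and did not pass (adjusted p = 0.113, 0.112 and 0.305). The same was asked of NRF2 targets, because osgn1, a growth inhibitor gene of that group singled out after its values were seen, rose 2.13-fold, from 14.4 ± 1.67 to 31.1 ± 0.566 (SD, n = 3; limma adjusted p = 0.00823), a call that ended without DMSO replicate 2 (0.0548). The mean of 13 other targets differed by 0.037 (SE 0.049), which argues against a response above 0.3 in the mean of that list; 7 of the 13 lay above 0, and a response of part of them stays open.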
